A study of Mus musculus with 12 samples.

How the data were processed

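RNA sequencing profiled 12 libraries from the brains of 8 mice. The animals carried a floxed Bmal1 gene (official symbol Arntl), which encodes a core transcription factor of the circadian clock, on a C57BL/6 background. Some also carried a tamoxifen-inducible Cre recombinase driven by Aldh1l1, a gene active in astrocytes. Per the labels' protocols, all animals received 2 mg of tamoxifen a day for 5 days at 2 months of age, and brains were taken at 7 months. After digestion, magnetic beads against ACSA-2, an epitope on the astrocyte surface protein encoded by Atp1b2, held back the astrocytes. The cells that the beads did not retain are called flowthrough. The titles of all flowthrough libraries also carry a letter b, whose meaning was not given in the sources used here, so anything that it marks is confounded with the fraction. RNA was amplified with a SMARTer kit. The strand setting of the counting was not given in the sources used here, so reads of a gene and of an antisense or overlapping neighbour may not be told apart.

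Groups were taken from the titles. Isolated astrocytes came from 3 Cre-negative animals (wild type, WT; numbers 201, 202 and 265) and 5 Cre-positive animals (astrocyte knockout, aKO; numbers 203, 205, 208, 221 and 222). Flowthrough came from WT 201 and 202 and from aKO 203 and 205, so 4 animals gave both fractions. The number in a title was read as the animal. The astrocyte library of animal 202 is named as wild type in its title but as knockout in its genotype field. It was kept as WT because its title, the genotype of the flowthrough of the same number and the numbers of samples in the series' design all give WT. It was also left out and counted as aKO.

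The deposited files give, per Ensembl gene, the read count, CPM (counts scaled to the library's total) and RPKM (reads scaled to the total and to gene length) that the authors computed. Per the submitters' processing notes, bcl2fastq, STAR 2.5.1a, Subread and featureCounts 1.4.6-p5 were used with the mouse genome GRCm38. The annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here. Every file holds the same 41388 genes. The deposited CPM equalled the count divided by the file's own total. The deposited CPM and RPKM entered only that check, and all tests used the deposited counts. GENCODE vM21 names were found for 40254 of the identifiers. The other 1134 held between 0.0782% and 0.116% of a library's counts and were kept in the tests. Coordinates are those of GRCm38.

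Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust dispersion, TMM normalization and the filterByExpr filter (minimum count 10, minimum total 15). P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The astrocyte comparison used the 8 astrocyte libraries. The other comparisons came from a fit of 4 groups to all 12 libraries: aKO against WT flowthrough, astrocytes against flowthrough with both genotypes weighted equally, and the difference between both genotype effects. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 4 tested genes. There were 35 lists, 18 of them for biological processes, 14 for cell type markers and 3 for sample quality or sex. Of their 505 distinct symbols, 1 was matched through a synonym (Chi3l1, now Chil1) and 1 was not found (Lhfpl3).

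The design, the lists, the alternatives and the rule for named genes were set before the data were examined, except where stated. The rule named Arntl; clock list members past the threshold; the 10 genes with the largest significant change in each direction, among genes with an official symbol, a mean log2 CPM of at least 3 and, for aKO astrocytes, no overlap between groups; up to 4 members with the smallest p in each list described; and Gfap, Bag3, Chil1, Aqp4, Atp1b2 and Aldh1l1 in every comparison. Some genes that the rule names, and some that passed over their list alone, are not reported here. The alternatives were DESeq2's size factors, no count filter, DESeq2 1.42.0, limma voom with sample weights, each library left out, library 202 as aKO, all libraries in 1 fit, covariates for other cell types' markers and for Xist, thinning to the smallest library, a block for the animal, and other list tests. Leaving out the libraries with high Xist, and leaving out aKO 222 and WT 265, were chosen after seeing the data. Flowthrough and astrocyte libraries of the same number come from the same brain. Their deviations from the group means correlated across genes with r of 0.0823, 0.424, 0.166 and 0.404 for animals 201, 202, 203 and 205. Each flowthrough group holds 2 libraries, whose deviations are exact opposites. Within a genotype, each r between different animals therefore only mirrors a same-animal r (-0.424 against 0.424 for astrocytes of 202). Across genotypes, r reached 0.311 (astrocytes of 203 with flowthrough of 202), so the pairing rests on the animal and not on these values. No pair of libraries of a group agreed within counting noise. Of the genes named below, Nr1d1, Per3, Dbp, Cxcl10, Timp1, Stub1, Mia, B3galt2, Entpd2, Gsg1, Psmb9, B2m and Dnajb6 overlap another protein-coding gene, and Gfap, Aldh1l1, Wee1, Cry2, Rora, Csnk1e, Reln, Rbfox3, Gad1, Npas2, Psmb8, Mog, Tmem212, Klf9 and Luzp2 overlap a noncoding or antisense gene or a pseudogene, so their counts are less certain.

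The tests were run first on simulated counts with the real means, dispersions and library sizes, in which 200 genes were changed. The changed genes were drawn only from genes with higher mean counts, so the shares found do not extend to genes with low counts. Each gene was simulated on its own, without differences between libraries that many genes share. The shares found and the false shares therefore need not hold for the real libraries. For aKO against WT astrocytes (18950 genes), 5.97% of genes changed 2-fold, 58.2% of those changed 4-fold and 97.0% of those changed 8-fold were found, and 10.1% of the calls were false. For aKO against WT flowthrough (20637 genes), the shares found were 0%, 5.97% and 24.2%. For astrocytes against flowthrough they were 5.97%, 73.1% and 95.5%. For the difference between the genotype effects they were 0%, 2.99% and 9.09%. The false share was 0% of 20 calls for flowthrough, 3.33% of 120 for astrocytes against flowthrough and 20% of 10 for the difference. The list test found the raised list in each simulation and called 0 of 34 unchanged lists, whose genes were simulated independently. The genes of the raised list were all changed 4-fold, so weaker shifts of a list were not tried.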

Results

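Gene expression was compared between isolated astrocytes of 5 aKO and 3 WT mice, and between the flowthrough cells of 2 aKO and 2 WT mice. Total counts ranged from 21816637 to 62655238 in the astrocyte libraries and from 33019572 to 53868165 in flowthrough. Mitochondrially encoded genes took 22.9% ± 8.33 (SD, n = 8) of the counts in astrocytes and 7.69% ± 3.74 (SD, n = 4) in flowthrough. Ttr, the transthyretin gene that choroid plexus epithelium expresses at very high levels, took 7.18% ± 5.47 (SD, n = 8) in astrocytes and 19.5% ± 9.81 (SD, n = 4) in flowthrough. Xist, which is transcribed from the inactive X chromosome of females, had 2044 and 972 counts in aKO astrocyte libraries 221 and 222 and at most 46 in the other 10. Libraries aKO 222 and WT 265 stood apart on the first principal component of the astrocyte libraries, which held 34.2% of the variance. The lists of genes and the comparisons below follow the question in the series' design, namely how astrocytes that have lost BMAL1 differ from wild-type astrocytes.

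In isolated astrocytes, 4 genes rose and 1 fell in aKO animals. Spon2, which encodes the secreted matrix protein spondin 2, rose from 1.13 ± 1.12 CPM (SD, n = 3) in WT to 82.1 ± 27.5 CPM (SD, n = 5) in aKO. Cxcl5, a neutrophil-attracting chemokine, rose from 1.33 ± 1.33 to 40.2 ± 21.7 CPM. Oas2, an interferon-induced 2'-5' oligoadenylate synthetase, rose from 1.48 ± 0.0950 to 15.7 ± 5.39 CPM, and Hebp2, a heme-binding protein, from 3.74 ± 0.374 to 25.8 ± 9.77 CPM. Rpe65, the retinoid isomerase of the visual cycle, fell from 15.6 ± 2.74 to 1.03 ± 0.644 CPM. Rpe65 lay under the expression level of the naming rule and was named after its values were seen. For each of the 5 genes, every aKO library lay on the same side of every WT library.

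**Figure D1:**
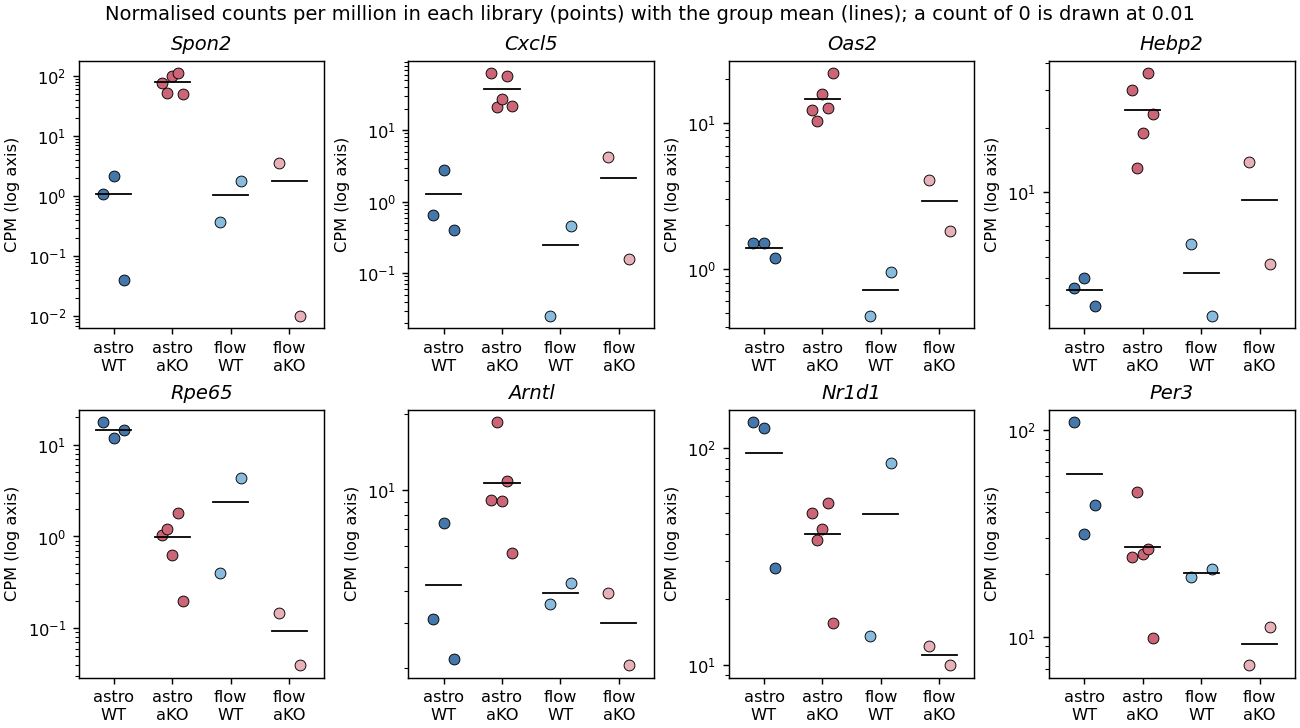
Normalised CPM on a log axis in each library (points), with all 12 libraries scaled together, with the group mean (lines), for the 5 genes that differed between aKO and WT astrocytes and for Arntl, Nr1d1 and Per3; a count of 0 is drawn at the bottom of the axis. The aKO astrocyte libraries lie above every WT astrocyte library for Spon2, Cxcl5, Oas2 and Hebp2, and below for Rpe65.

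The 5 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment among 18950 genes. The log2 fold changes were 6.15 (SE 0.80) for Spon2 and 3.40 (SE 0.41) for Oas2, and -3.88 (SE 0.50) for Rpe65, each with an edgeR adjusted p of 0.00760. Cxcl5 changed by 4.91 (SE 0.69; edgeR adjusted p = 0.0152) and Hebp2 by 2.78 (SE 0.41; edgeR adjusted p = 0.0201). Without WT 202, the estimates were 7.04 for Spon2 and 6.12 for Cxcl5. With library 202 counted as aKO, they were 6.78 for Spon2, 5.88 for Cxcl5 and -2.53 for Rpe65, none past the threshold. Over 19 alternatives, Oas2 passed in 17, Spon2 and Rpe65 in 15, Cxcl5 in 13 and Hebp2 in 10. In GRCm38, Spon2 lies on chromosome 5 from 33213518 to 33218238, Cxcl5 on chromosome 5 from 90759299 to 90761625 and Oas2 on chromosome 5 from 120730333 to 120749853. Hebp2 lies on chromosome 10 from 18540123 to 18546076 and Rpe65 on chromosome 3 from 159599233 to 159624799. None of these 5 genes overlaps another annotated gene, and the counts cover their exons. In all, 299 genes had an unadjusted p under 0.05, which is 1.58% of those tested, and 266 (1.4%) had groups without overlap, where chance gives 3.57%. Without WT 201, edgeR called 0 genes (401 at an unadjusted p under 0.05), without aKO 205 it called 2 and without WT 265 it called 3. With library 202 counted as aKO it called 0 (803 at an unadjusted p under 0.05), in the fit of all 12 libraries 1, without libraries 222 and 265 3 and without the count filter 8, and DESeq2 called 15.

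Arntl, the gene targeted by Cre, was measured at 3.10, 7.44 and 2.16 CPM in WT astrocytes 201, 202 and 265, with all 12 libraries scaled together. It was measured at 9.15, 18.5, 9.04, 10.9 and 5.68 CPM in aKO astrocytes 203, 205, 208, 221 and 222. In flowthrough it stood at 3.56 and 4.33 CPM in WT 201 and 202 and at 3.95 and 2.04 CPM in aKO 203 and 205. The log2 fold change in astrocytes was 1.33 (SE 0.47), which did not pass (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.9997). With each library left out, the estimate ran from 1.05 (without aKO 205) to 2.00 (without WT 202), and it was 1.92 with library 202 counted as aKO. Arntl lies on chromosome 7 from 113207465 to 113314122. A count over the whole gene also takes reads from exons that Cre leaves in place, so these values check neither the deletion nor the genotype labels.

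By edgeR, no member of the core clock list or the clock output list passed over all genes in aKO astrocytes. In the core list (18 genes), 7 estimates lay above 0 and 11 below, with 0 genes past the threshold when adjusted over the list alone. Npas2, the paralog of Clock, had a log2 fold change of 1.16 (SE 0.43) and Cry1, a repressor of the clock, 0.71 (SE 0.34). Nr1d1, which encodes the repressor REV-ERBα, had -1.19 (SE 0.46) and Per3 had -1.16 (SE 0.46). In the output list (15 genes), 3 estimates lay above 0 and 12 below, and 1 gene passed when adjusted over the list alone. This was Cdkn1a, the cell cycle inhibitor p21, at 22.4 ± 4.82 CPM (SD, n = 3) in WT and 90.3 ± 28.0 CPM (SD, n = 5) in aKO. Its log2 fold change was 2.01 (SE 0.39), with an edgeR quasi-likelihood p, Benjamini-Hochberg adjusted over the list alone, of 0.00178 and of 0.328 over all genes. Cdkn1a passed over all genes by DESeq2 (adjusted p = 8.49e-05), the only 1 of its 19 alternatives in which it did, with adjusted p-values of up to 0.9999 in the others. Chil1, which encodes a chitinase-like glycoprotein of astrocytes, had -1.14 (SE 0.39), Dbp -0.76 (SE 0.36) and Wee1 -0.85 (SE 0.59). The camera test in limma gave Benjamini-Hochberg adjusted p-values of 0.587 for the core list and 0.0840 for the output list. Nr1d1, Per3 and Dbp overlap Thra, Camta1 and Sphk2, so their counts are less certain.

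**Figure D2:**
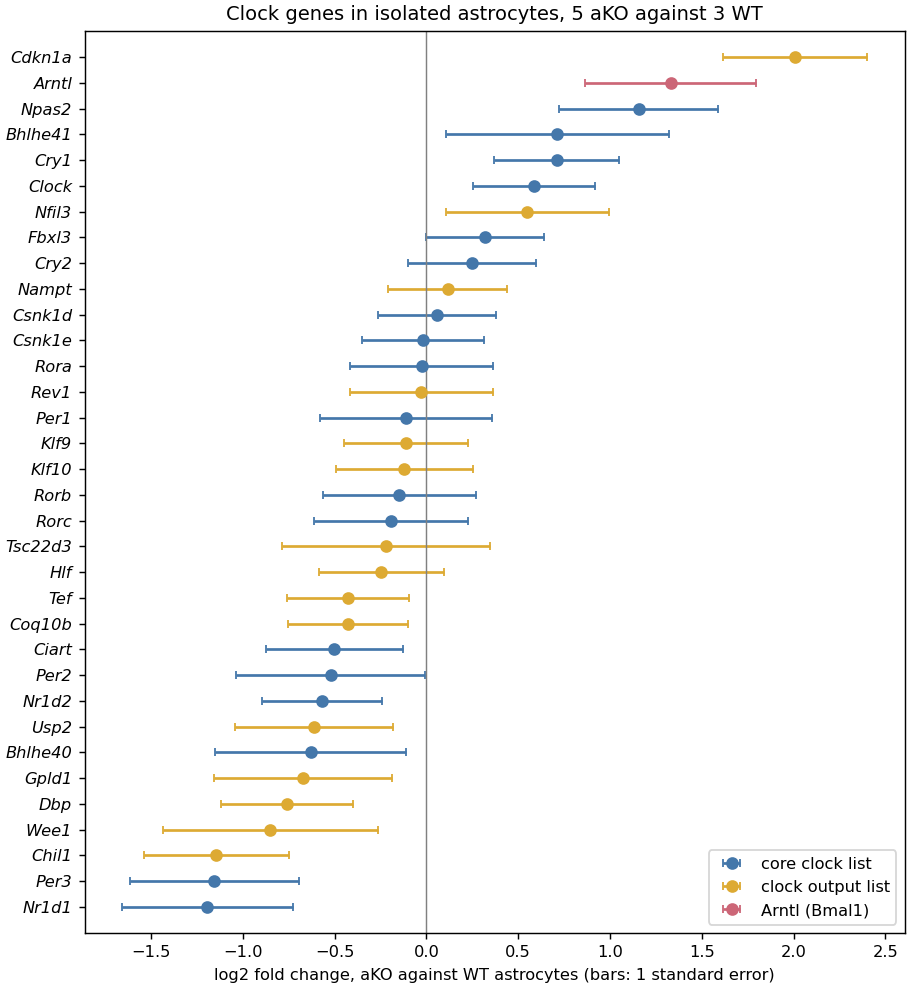
Log2 fold changes of aKO against WT astrocytes (horizontal axis; bars show 1 standard error) for Arntl and for the members of the core clock and clock output lists. Estimates run from -1.19 for Nr1d1 to 2.01 for Cdkn1a.

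With camera's preset correlation, 3 lists of markers of other brain cells passed between aKO and WT astrocyte libraries, and none of the 3 held with an estimated correlation. All 14 oligodendrocyte markers lay higher in aKO, with a median of 1.59-fold, and all 14 endothelial markers lay higher, with a median of 1.34-fold. All 11 ependymal markers lay lower, with a median of 1.68-fold. By member, Mog had a log2 fold change of 1.05 (SE 0.46), Mag 0.96 (SE 0.48), Mal 0.93 (SE 0.45) and Cldn11 0.90 (SE 0.46). Among endothelial markers, Cldn5 had 1.14 (SE 0.51), Vwf 0.62 (SE 0.42), Tek 0.45 (SE 0.32) and Emcn 0.59 (SE 0.42). Among ependymal markers, Mia had -1.08 (SE 0.56), Ak7 -0.73 (SE 0.39), Tmem212 -0.96 (SE 0.61) and Cfap126 -0.82 (SE 0.52). Without WT 265, Mia turned to 0.0927 and Tmem212 to 0.0523, and Cfap126 had -0.12 and Ak7 -0.78. None of these genes passed alone. With the preset correlation, camera gave Benjamini-Hochberg adjusted p-values of 4.9e-06, 1.6e-04 and 6.1e-04 for the oligodendrocyte, endothelial and ependymal lists. With an estimated correlation, the adjusted p-values were 0.854, 0.80 and 0.854, so none of the 3 calls held, and fry called 0 lists. The ependymal call was lost without WT 265 (camera adjusted p = 0.545) and the endothelial call without WT 202 (camera adjusted p = 0.0977).

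Genes tied to astrocyte reactivity and to chaperone-assisted autophagy showed no change past the threshold. The simulated astrocyte test found 5.97% of 2-fold changes, and the estimates in this paragraph are under 2-fold, so changes of their size could be missed. Gfap, the intermediate filament of reactive astrocytes, stood at 105 ± 80.0 CPM (SD, n = 3) in WT and 184 ± 129 CPM (SD, n = 5) in aKO, a log2 fold change of 0.81 (SE 0.58). In the pan-reactive list (13 genes), Osmr had 0.50 (SE 0.39), Cxcl10 0.58 (SE 0.59) and Timp1 0.59 (SE 0.78). The sign of Cxcl10, Timp1 and Aqp4 turned in some alternatives, given with the other settings. In the chaperone and autophagy list (13 genes), Bag3, a co-chaperone of selective autophagy, had 0.50 (SE 0.39), Dnajb6 0.83 (SE 0.47), Stub1 0.60 (SE 0.41) and Hdac6 0.37 (SE 0.33). Of the isolation and lineage genes, Atp1b2 had 0.41 (SE 0.46), Aqp4 -0.03 (SE 0.48) and Aldh1l1 -0.79 (SE 0.57). Camera's Benjamini-Hochberg adjusted p-values were 0.656 for the pan-reactive list and 0.259 for the chaperone and autophagy list.

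None of the other 28 lists passed in aKO astrocytes. Camera's Benjamini-Hochberg adjusted p was 0.0840 for MHC class I, immediate early, mural cell and sex-linked genes, 0.0990 for cell cycle and border macrophage genes, and 0.101 for interferon, A1 reactive and neuron genes. It was 0.104 for mitochondrially encoded genes, 0.118 for cholesterol synthesis, 0.279 for neuroblasts, 0.298 for glutamate and GABA handling, and 0.331 for glycolysis and for astrocyte markers. It was 0.443 for lysosomal genes, 0.595 for A2 reactive genes, and 0.656 for core autophagy, synapse and phagocytosis, leukocyte, oligodendrocyte precursor and choroid plexus genes. It was 0.758 for fibroblasts, 0.821 for erythrocytes, 0.867 for heat shock, 0.921 for nuclear oxidative phosphorylation and for microglia, and 0.927 for antioxidant genes.

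In flowthrough, no gene changed in aKO animals past the threshold. The largest estimates among the genes named in every comparison were -1.41 (SE 0.98) for Aqp4, -1.29 (SE 1.02) for Gfap and -1.03 (SE 0.89) for Aldh1l1 on the log2 scale. Without flowthrough WT 202, Gfap turned to 1.38 and Aldh1l1 to 0.58, and Aqp4 ran from -4.86 (without flowthrough aKO 203) to -0.18 (without flowthrough WT 202). Chil1 had -0.94 (SE 0.63), Bag3 0.62 (SE 0.56), Arntl -0.31 (SE 0.63) and Atp1b2 -0.05 (SE 0.65). The 5 genes called in astrocytes had the same sign in flowthrough, which was looked at after their values were seen. Rpe65 had -4.42 (SE 1.10), Oas2 2.12 (SE 0.58), Cxcl5 3.25 (SE 1.30), Hebp2 1.20 (SE 0.60) and Spon2 0.86 (SE 1.32). Over these 5 alone, edgeR's quasi-likelihood p with Benjamini-Hochberg adjustment was 0.00462 for Rpe65, 0.00514 for Oas2, 0.0408 for Cxcl5, 0.0760 for Hebp2 and 0.524 for Spon2. These flowthrough libraries come from animals whose astrocytes are also in the astrocyte comparison. Of the 35 lists, astrocyte markers were lower, with 19 of 20 members below 0 and a median of 2.14-fold lower. Camera gave them a Benjamini-Hochberg adjusted p of 0.0457, and an adjusted p of 0.947 with an estimated correlation. The call was lost without flowthrough WT 202, where its direction turned (camera adjusted p = 0.391), and without flowthrough aKO 205 (0.951), or astrocyte library aKO 205 (0.0571), aKO 208 (0.0538) or aKO 222 (0.0521). By edgeR, 0 of 20637 genes passed and 817 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Without the count filter, 45 passed.

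The genotype effect did not differ between the fractions past the threshold for any gene. By edgeR, 0 of 20637 genes passed and 499 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. The effect in astrocytes minus that in flowthrough was 1.62 (SE 0.79) for Arntl, 2.09 (SE 1.27) for Gfap and 1.36 (SE 1.21) for Aqp4 on the log2 scale. It was 0.46 (SE 0.80) for Atp1b2, 0.21 (SE 1.08) for Aldh1l1, -0.10 (SE 0.70) for Bag3 and -0.23 (SE 0.77) for Chil1. For Spon2 it was 5.26, with an edgeR quasi-likelihood p after Benjamini-Hochberg adjustment of 0.956. With the animal as a block on the 8 libraries of the 4 animals with both fractions, 1 gene passed, and 1 passed in the same libraries without the block. Without the count filter, 40 passed.

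Microglial and leukocyte markers were lower in astrocytes than in flowthrough. Microglial markers took 1.82% ± 0.572 (SD, n = 4) of the counts in flowthrough and 0.101% ± 0.0212 (SD, n = 8) in astrocytes, and leukocyte markers 0.276% ± 0.0958 and 0.0178% ± 0.0113. All 16 microglial and all 12 leukocyte markers had estimates below 0 in astrocytes, and 16 and 11 of them passed edgeR's threshold. Astrocyte markers took 1.61% ± 0.613 in astrocytes and 0.497% ± 0.476 in flowthrough. All 20 had estimates above 0, and 13 passed the threshold. Oligodendrocyte markers were also higher in the astrocyte fraction, at 1.23% ± 0.666 against 0.287% ± 0.270. All 14 had estimates above 0, and 11 passed the threshold. As lists, with an estimated correlation, camera's adjusted p was 0.357 for astrocyte and for oligodendrocyte markers. It was 0.0201 for microglial and 0.0239 for leukocyte markers. By fry, the adjusted p was 0.00769 for astrocyte and 0.00683 for oligodendrocyte markers.

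**Figure D3:**
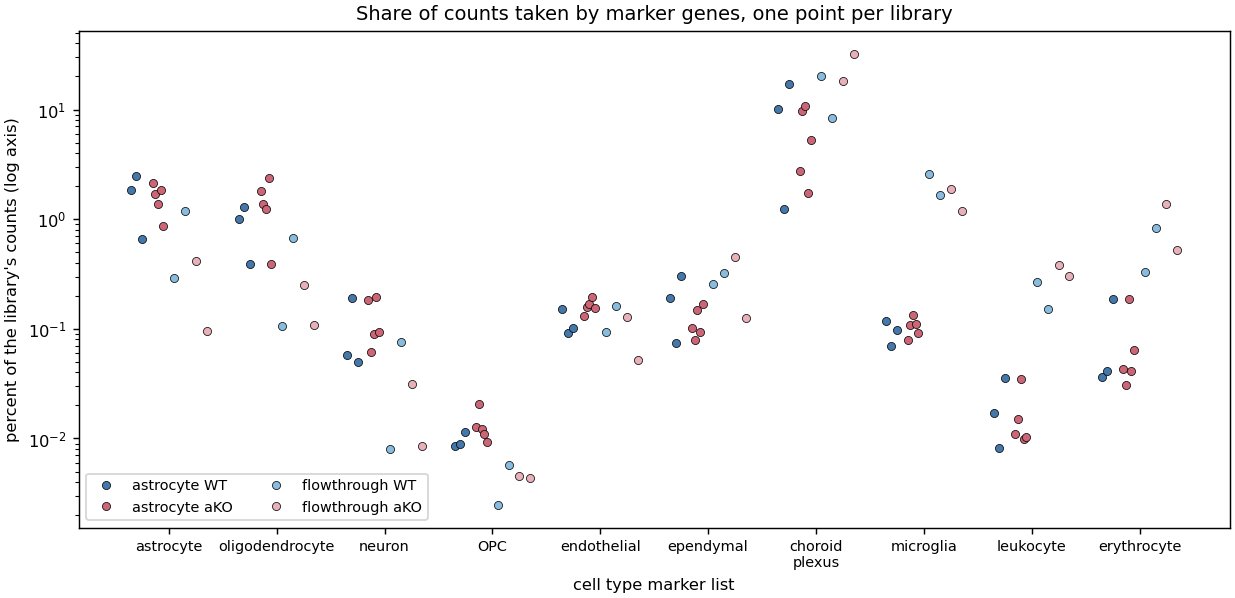
Percent of each library's counts taken by the genes of 10 marker lists (log axis), with 1 point per library, for astrocytes and flowthrough of both genotypes. Microglial, leukocyte and erythrocyte markers lie higher in flowthrough and astrocyte and oligodendrocyte markers are on average higher in astrocytes, with overlap: flowthrough WT 202 (1.18% and 0.678%) lies above astrocyte libraries aKO 222 (0.875% and 0.392%) and WT 265 (0.661% and 0.391%) in these markers.

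In all, 3517 of 20637 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1758 higher and 1759 lower in astrocytes. With the animal as a block on the 8 libraries of the 4 animals with both fractions, 5951 passed, and 3562 passed in the same libraries without the block. Without flowthrough WT 201 there were 1691, and without flowthrough aKO 205 there were 2136.

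Elane, neutrophil elastase, was among the genes with the largest fall in astrocytes. It stood at 0.138 ± 0.270 CPM (SD, n = 8) in astrocytes and 44.4 ± 42.9 CPM (SD, n = 4) in flowthrough, a log2 fold change of -8.92 (SE 1.05). Prss34, a mast cell protease, had -9.45 (SE 0.86), the immunoglobulin genes Igkv6-15 and Igha -9.83 (SE 1.54) and -7.15 (SE 1.5), and Rasal3 and Plac8 -6.10 (SE 0.54) and -5.85 (SE 0.45). Selplg, the P-selectin ligand, had -5.65 (SE 0.43), Gsg1 -5.65 (SE 0.43), and the chemokines Ccl5 and Ccl4 -5.29 (SE 0.61) and -5.29 (SE 0.49). Igha passed in 16 of its 19 alternatives. Igkv6-15 belongs to a family of near-identical segments whose reads the counting could split. Among microglial markers, Siglech changed by -4.86 (SE 0.36), Tmem119 by -5.22 (SE 0.47) and C1qc by -4.68 (SE 0.43) on the log2 scale. Among leukocyte markers, Cd3g changed by -4.44 (SE 0.48), Nkg7 by -5.28 (SE 0.59), S100a8 by -4.31 (SE 0.57) and Coro1a by -3.47 (SE 0.39).

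The genes with the largest rise in astrocytes were Tph1 (5.04, SE 1.51, log2), F3 (4.56, SE 0.84), Gabra6 (4.49, SE 1.04), Luzp2 (4.38, SE 0.92) and B3galt2 (4.29, SE 0.68). They were followed by Slitrk2 (4.19, SE 0.45), Cdh10 (4.05, SE 0.57), Gdf10 (4.04, SE 0.39), Entpd2 (3.97, SE 0.67) and Cplx3 (3.96, SE 1.17). The order and size of these estimates moved with the setting, over the alternatives from 3.58 to 5.47 for Tph1, 4.11 to 6.17 for F3, 3.77 to 7.66 for Gabra6 and 3.89 to 6.96 for Luzp2. Leaving out flowthrough WT 202 gave the highest values of F3 and Luzp2, and leaving out flowthrough aKO 203 that of Gabra6. F3, tissue factor, reached 464 ± 266 CPM (SD, n = 8) against 31.3 ± 49.6 CPM (SD, n = 4). Of 19 alternatives, Tph1 passed in 10, and Cplx3 passed in 10 of the 18 that gave an adjusted p. Gfap, Aldh1l1 and Gad1 passed in 14, Syt1 in 15 and each other gene named in this paragraph in at least 17. Tph1, the peripheral tryptophan hydroxylase, stood at 19.97 ± 38.2 CPM in astrocytes, a spread larger than its mean. Gabra6 is a GABA receptor subunit of cerebellar granule neurons. Of the astrocyte markers, Fgfr3 rose by 3.35 (SE 0.56), Slc4a4 by 3.07 (SE 0.57), Aqp4 by 2.52 (SE 0.68), Atp1b2 by 2.45 (SE 0.45), Gfap by 2.33 (SE 0.70) and Aldh1l1 by 2.06 (SE 0.60). Of the oligodendrocyte markers, Gjc3 rose by 2.32 (SE 0.43), Cldn11 by 1.98 (SE 0.44) and Mal by 1.96 (SE 0.44). Neuronal Gad1 rose by 2.17 (SE 0.63), Reln by 2.09 (SE 0.39), Rbfox3 by 2.08 (SE 0.52) and Syt1 by 2.08 (SE 0.59).

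Some clock genes also differed between the fractions. Rorb rose by 3.16 (SE 0.59) on the log2 scale in astrocytes, Gpld1 by 2.44 (SE 0.53), Npas2 by 1.73 (SE 0.44), Rora by 1.60 (SE 0.38), Per3 by 1.55 (SE 0.42), Hlf by 1.24 (SE 0.33), Cry2 by 1.22 (SE 0.32), Cry1 by 0.90 (SE 0.29) and Klf9 by 0.89 (SE 0.29). Cry1 passed in 4 and Klf9 in 6 of 19 alternatives, and each other gene in this paragraph that passed did so in at least 17. Csnk1e changed by -1.59 (SE 0.29) and Klf10 by -1.38 (SE 0.35). In the core list, 6 genes passed upward and 1 downward over all genes, and 8 and 1 adjusted over the list alone. The other 11 of 18 did not pass over all genes. Camera called this list (adjusted p = 0.0166), but not with an estimated correlation (0.514). Gpld1, Hlf, Klf9 and Klf10 belong to the output list, in which 3 genes passed upward, 1 downward and 11 of 15 did not. Camera did not call the output list (adjusted p = 0.307). Arntl had 0.95 (SE 0.40), Bag3 0.16 (SE 0.35) and Chil1 0.22 (SE 0.39), none past the threshold. With the animal as a block on 8 libraries, Arntl passed at 1.23 (SE 0.39; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0393), and in the same libraries without the block it had 1.31 (SE 0.45; edgeR adjusted p = 0.0655). Over its 19 alternatives, Arntl's edgeR, DESeq2 or limma adjusted p ran from 0.0393 to 0.323.

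Camera called 16 of the 35 lists between the fractions, 8 higher and 8 lower in astrocytes. Lower lists were microglia (limma camera, Benjamini-Hochberg adjusted p = 6.1e-23), leukocyte (1.2e-12), immediate early genes (1.5e-06), MHC class I (1.5e-05), cell cycle (1.5e-05), lysosome (5.4e-04), erythrocyte (5.4e-04) and ependymal (0.00318). With an estimated correlation, the camera adjusted p was 0.0201 for microglia and 0.0239 for leukocyte lists, and 0.255 to 0.514 for the other 6, whose calls did not hold in that setting. By fry, another list test in limma, all 8 passed except ependymal (fry adjusted p = 0.0762). Higher lists were astrocyte (5.0e-10), mitochondrially encoded (1.1e-06), oligodendrocyte (1.1e-06), cholesterol synthesis (1.0e-05), glutamate and GABA handling (1.1e-05), neuron (1.2e-05), oligodendrocyte precursor (0.00318) and core clock (0.0166). For these 8 lists the camera adjusted p was 0.357 to 0.514 with an estimated correlation, so none of the calls held in that setting. By fry all 8 passed, with adjusted p-values from 0.00683 (oligodendrocyte) to 0.0289 (neuron and core clock). Over 17 alternatives, the core clock list was called in 15 and the astrocyte list in 16. In the MHC class I list, 6 of 13 genes passed, all lower, among them H2-M3 at -1.91 (SE 0.38), Psmb9 at -1.87 (SE 0.39), Psmb8 at -1.60 (SE 0.28) and B2m at -1.94 (SE 0.45). In the cholesterol list, 11 of 20 genes passed, all higher. In the glutamate and GABA list, 6 of 15 genes passed, all higher. Of the immediate early genes, 10 of 18 passed lower and 1 higher.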

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

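The covariates for markers and for Xist were planned settings, while their use as tests of the 5 genes below, and the tests on the libraries with high Xist, on library 202, on the share of astrocytes and on WT 265, were chosen only after the results they bear on were seen.

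Among the 5 aKO astrocyte libraries, library 222 stood far from the others in the mean log2 CPM of the glycolysis list, at 6.58 against 7.10 to 7.29. Its gap to the nearest library was 0.73 of the whole range. Of 75 measures examined in this way, 1 stood out, where chance gives 3.75. The other groups were too small for this check. In the glycolysis list, astrocyte library WT 265 lay lower still, at 6.07, against 7.265 and 7.398 in WT 201 and 202, so library 222 was not the only low one.

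Spon2, Cxcl5, Oas2, Hebp2 and Rpe65 differed between aKO and WT astrocytes. All 5 were still called without the 2 libraries with high Xist, which argues against a difference in sex as the whole cause. With Xist as a covariate 4 were called, and Hebp2 moved from 2.78 (SE 0.41) to 2.58 (SE 0.44), a smaller estimate with a larger error. All 5 were also called with the first component of the other cell types' markers as a covariate. That component ran from -11.05 to 8.72 in WT and from -4.31 to 6.39 in aKO libraries. It did not separate the groups, so its covariate could not remove a difference between them, and carried-over RNA stays open. Of the 56 splits of the 8 libraries into 3 and 5, 3 gave at least 5 genes, the real one included, so chance is not excluded. The highest other split gave 881 genes with libraries 208, 222 and 265 as the group of 3, which points to a structure of the samples, since 222 and 265 also stood apart on the first principal component. All 5 genes had the same sign in flowthrough, with log2 fold changes from 0.86 for Spon2 to 3.25 for Cxcl5, and -4.42 for Rpe65. The changes are therefore not shown to be particular to astrocytes. An effect of the genotype, and any other difference between the groups of animals that goes with it, such as litters or collection times, stay open and were not tested.

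With the astrocyte library 202, which carries labels for both genotypes, left out, edgeR called 4 genes, and the library lay nearer the aKO mean in 0 of the 4. Spon2 stood at a log2 CPM of 1.23 in library 202, against a mean of -1.55 in the other WT and 6.29 in the aKO libraries, and Rpe65 at 3.64 against 4.11 and -0.15. Going the other way, the log2 difference between the 2 sets of clock genes was -2.11, nearer the aKO mean of -1.52 than the other WT libraries (-3.13 and -2.82), though outside the aKO range of -1.71 to -1.34. Arntl, given above, also lay within the range of the aKO astrocytes in library 202 and above the other WT astrocytes. In the difference between the 2 sets of clock genes, the flowthrough of animal 202 stood at -2.46. That was near flowthrough WT 201 (-2.66) and away from flowthrough aKO 203 and 205 (-1.74 and -1.85). By the 4 called genes astrocyte library 202 lay with WT, and by the clock genes, which did not pass alone, it lay nearer aKO. None of these genes is shown to follow the genotype, so they do not decide whether this is an aKO library under a WT title. An exchange with another WT sample stays open and was not tested.

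The oligodendrocyte and endothelial lists lay higher and the ependymal list lower in aKO astrocytes by limma camera with the preset correlation, but not with an estimated correlation (limma camera adjusted p = 0.854, 0.80 and 0.854), and the endothelial call was lost without WT 202 (limma camera adjusted p = 0.0977, with a range of 2.69e-05 to 0.933 over 15 alternatives). At least 3 lists were called in 54 of the 56 splits, with up to 16 in the other splits, so chance is not excluded. The ependymal call was lost without WT 265 (limma camera adjusted p = 0.545, with a range of 1.57e-08 to 0.942 over 15 alternatives), so ependymal cells carried over into that library could account for it. A lower share of astrocytes would raise the markers of all other cells alike. The oligodendrocyte and ependymal changes lay 1.19 apart on the log2 scale, with an exact two-sided permutation p of 0.179, so a lower share cannot be told apart from separate changes with these 8 libraries.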

How the results depend on the processing

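Leaving out the 2 libraries with high Xist, and leaving out 222 and 265, were chosen only after seeing the data. Where no cause is named, the cause was not tested.

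Arntl kept its direction and stayed short of the threshold in all 19 alternatives for aKO astrocytes. The number of genes called there was 8 with no low-count filter, 15 by the DESeq2 Wald test, 1 with all 12 libraries in 1 fit, 3 without libraries 222 and 265, and 0 by edgeR with library 202 counted as aKO (803 at an unadjusted p under 0.05). Leaving out each library gave 0 (without WT 201) to 5, with 2 without aKO 205 and 3 without WT 265. In flowthrough, 45 were called with no filter and 0 to 1 (without flowthrough WT 201) with each library left out, and for the difference between fractions 40 with no filter. With the animal as a block on 8 libraries, 1 gene was called for that difference and 1 without the block, and 5951 between the fractions. Beyond these counts and Arntl between the fractions, which passed with the block at 1.23, the block changed no call of a named gene and no count of lists by over 1.5 times. Between the fractions, leaving out each library gave 1691 (without flowthrough WT 201) to 4107 (without flowthrough WT 202), and 2136 without flowthrough aKO 205.

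For lists in aKO astrocytes, 0 were called with an estimated correlation, 0 by fry, 5 with library 202 as aKO, 12 with the marker covariate, 7 without the high-Xist libraries, 11 without 222 and 265, and 3 (without aKO 208) to 15 (without aKO 203) with each library left out. In flowthrough, 0 were called with an estimated correlation, 0 by fry and 0 to 5 (without flowthrough WT 201 or astrocyte WT 265) with each library left out. Between the fractions, 2 held with an estimated correlation, and fry called 16, of which 15 were shared with camera.

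Log2 estimates that turned sign had not passed the threshold. In astrocytes, limma voom gave 0.18 for Aqp4 and -0.40 for Timp1. Library 202 as aKO gave 0.44 for Aqp4 and 0.37 for Aldh1l1. The Xist covariate gave 0.24 for Aqp4, -0.0389 for Cxcl10 and -0.73 for Timp1. Without the high-Xist libraries, Aqp4 had 0.0523 and Timp1 -0.49, and without 222 and 265 Timp1 had -0.0307. In flowthrough, voom gave 0.18 for Atp1b2. For the difference between fractions, voom gave -0.045 for Aldh1l1, library 202 as aKO 0.83 for Chil1, the animal block 0.34 for Bag3 and -0.0381 for Aldh1l1, and the same 8 libraries without the block 0.25 for Bag3.

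With each library left out, astrocyte estimates ran from -0.42 to 0.33 for Aqp4, -0.0275 to 0.76 for Cxcl10, -0.28 to 0.89 for Timp1, -1.54 to 0.0927 for Mia and -1.39 to 0.052 for Tmem212. Flowthrough estimates ran from -0.92 to 0.0025 for Arntl, -2.74 to 1.38 for Gfap, -0.28 to 1.10 for Bag3, -0.74 to 1.06 for Atp1b2 and -1.83 to 0.58 for Aldh1l1. Between fractions they ran from -0.10 to 0.59 for Bag3 and -0.0507 to 0.58 for Chil1. For the difference they ran from -0.59 to 3.54 for Gfap, -0.57 to 0.81 for Bag3, -0.86 to 0.57 for Chil1, -0.65 to 1.17 for Atp1b2 and -1.40 to 1.02 for Aldh1l1. A group of 2 then holds 1 library, assumed to vary like the others.

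Values of the named genes kept direction and side of the threshold in 639 cases in astrocytes, 120 in flowthrough, 1048 between fractions and 114 for the difference; 25 in astrocytes and 86 between fractions lost the threshold, and 1 in astrocytes (Cdkn1a by DESeq2) and 1 between fractions (Arntl with the block) gained it. DESeq2 gave no adjusted p for Wee1 in astrocytes or Cplx3 between fractions, which are left out. With 2 libraries a group, the simulated flowthrough test found 24.2% of 8-fold and 0% of 2-fold changes, so changes of the latter size were not detectable.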

Other observations

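The tests in this part on clock genes, on Slc41a3, on chromosome 5 and on fractions swapped within animals were chosen only after the values they bear on were seen.

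In aKO astrocytes, Arntl, Npas2 and Cry1 had estimates above 0 and Nr1d1, Per3 and Dbp below 0. A hypothesis is that loss of BMAL1 activity lowers its E-box targets and releases genes repressed by NR1D1. The mean log2 CPM of 6 genes of the second kind minus that of 11 genes of the first kind was -2.69 ± 0.52 (SD, n = 3) in WT and -1.52 ± 0.16 (SD, n = 5) in aKO astrocytes, a difference of 1.17 (exact two-sided permutation p = 0.0179, the smallest that 56 splits can give). That form holds the 6 genes in which the pattern was seen, so it decides nothing. With those left out, 3 genes minus 8 genes differed by 0.58 (exact two-sided permutation p = 0.0357), in the direction that the hypothesis gives. These genes were chosen after the values were seen and come from the same libraries, so this is no independent test and does not decide either. The hour of brain collection was not given in the sources used here, and a difference in it between the groups could shift the same genes and stays open. In flowthrough, the full difference was -2.56 in WT and -1.79 in aKO (n = 2 each, the same animals). A shift in the same direction was thus seen in these flowthrough libraries, but it was not tested. Of the 6 genes of the pattern, Arntl changed sign there, at -0.31 on the log2 scale. Npas2 (0.84), Cry1 (0.83), Nr1d1 (-2.075), Per3 (-1.07) and Dbp (-0.31) kept their signs. Flowthrough also held astrocyte markers (mean 0.497% of counts), so these values cannot show whether the shift lies outside astrocytes. The source of the shift was not tested.

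Slc41a3, on chromosome 6 from 90604725 to 90646412, lies next to Aldh1l1, whose sequence drives the Cre transgene. It had a log2 fold change of 1.89 (SE 0.48) in aKO astrocytes, which did not pass (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.9997). Extra copies carried with the transgene could raise it in every cell type. In flowthrough the change was 0.69, with a 95% interval of -0.51 to 1.89 that holds both 0 and the astrocyte change, so the hypothesis stays open. The neighbours Klf15, Aldh1l1 and Iqsec1 had -0.57, -0.79 and 0.12 in astrocytes. In flowthrough, neighbours also lay above Slc41a3, with 1.10 for Zxdc, 1.46 for Gm8724 and 1.004 for Iqsec1 (95% interval 0.12 to 1.89).

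Of the 5 genes called in aKO astrocytes, 3 lie on chromosome 5. A stretch of chromosome 5 linked to the genotype could give such a grouping. Among the other genes with an unadjusted p under 0.05, 15 of 294 (5.10%) lie there, against 6.11% of the genes tested (Fisher's exact two-sided p = 0.540), so no excess was seen over the whole chromosome. The 3 genes lie between positions 33213518 (Spon2) and 120749853 (Oas2), so a short stretch would not hold them all, and a long one is neither shown nor excluded by this test.

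Between astrocytes and flowthrough, 3517 genes were found. Of 100 splits of the 12 libraries drawn at random, with the genotypes shuffled too, 2 gave at least as many, the real one included. So large a count was thus rare among splits that leave the animals out of account. Such splits do not keep the pairs of libraries from the same animal, so they do not exclude chance for this design. The highest other split gave 4112 genes, and it kept flowthrough WT 201, aKO 203 and aKO 205 together and exchanged only flowthrough WT 202 for astrocyte library aKO 222. Among the 16 ways of swapping the fractions within the 4 animals that gave both, which all part as many pairs as the real one, the highest other gave 1 gene, and these are too few for a share under 0.05. At least 16 lists were called in 9 of the 100 splits, with up to 19 in the other random splits and 17 in the swaps, so for the number of lists chance is not excluded.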
